A study of Mus musculus with 4 samples.

How the data were processed

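Messenger RNA sequencing had been carried out on mouse LSK cells, the lineage-negative, Sca-1-positive and c-Kit-positive fraction that holds haematopoietic stem cells and early progenitors. The labels give a C57BL/6 strain and 2 genotypes, Setd2f/f (wild-type Setd2) and Setd2D/D (Setd2 knockout), with 2 libraries each. Total RNA was purified on micro-scale columns and libraries were made by a standard Illumina procedure, per the labels' protocols. Whether RNA strand was kept, which exons are deleted and how many mice stand behind a library are not given in the sources used here. Because nothing says that the replicates came from separate mice, p-values for single genes measure only the spread between these libraries, which may be technical.

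The authors deposited a table of TPM values (length-normalised shares of the transcripts in a library) for 46517 genes in the 4 libraries. The tools cutadapt, RSEM and edgeR and the mm10 build are named, without roles or versions, per the submitters' processing notes. TPM divides each gene's estimated reads by its effective length and scales every library to the same total, so that each value depends on all the others in its library. The authors' deposited table of the comparison gives, for 23955 genes, a fold change as a ratio, a log2 fold change, the mean log2 CPM, an F score, a p-value and an FDR. Its p-values, as deposited, had a median ratio of 1.00 to the chi-square tail of the deposited F, so that the F was read with almost no allowance for the uncertainty of the variance. Values from the authors' deposited table are named as such and carry no error of their own here. In 5 rows of the TPM table and 2 rows of the comparison a comma in the gene name had shifted the fields by 1 column, and the fields were joined again.

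Neither table holds counts, so the test was made on a log scale. Genes with TPM of at least 1 in at least 2 libraries were kept (14755 genes), values were transformed to log2(TPM + 1), and limma 3.58.1 in R 4.3.3 was fitted with 1 term for genotype, moderated variances with an abundance trend, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale are Setd2D/D minus Setd2f/f and understate the change of genes near the pseudocount. With 2 libraries against 2, an exact permutation test cannot go below p = 0.33, so the limma p-values rest on variance pooled across genes. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over 34 lists. An estimated correlation and fry were the alternatives. At the preset correlation, camera compares the members of a list with the other genes. Its p-values there, however small, do not measure the spread between libraries. With the estimated correlation, camera relies on the residual degrees of freedom, which are few with 2 libraries against 2. The adjusted p was then at least 0.822 for all 34 lists. For heme synthesis the camera p rose from 0.0470 to 0.169 although its estimated correlation was -0.022. A call lost under that setting therefore does not by itself show that correlation between members had made the call. Where the estimate was high, correlation may have made it. The estimate was 0.59 for MYC ribosome biogenesis, 0.64 for mitochondrially encoded and 0.31 for granulocyte-monocyte genes. Few degrees of freedom and correlation were not separated as reasons for a lost call. For each list the members past the threshold were also counted adjusted over the list alone.

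The groups, the test, the 34 lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named Setd2, then the 10 largest rises and 10 largest falls among genes past adjusted p = 0.05 with a mean TPM of at least 5 and both libraries of 1 genotype on the same side of both libraries of the other, passing over gene models without a proper symbol and pseudogenes. Where fewer than 10 passed, the smallest p-values filled the rest and are said not to pass. It also named a set of fixed regulators and up to 4 members per list with the smallest p and a mean TPM of at least 1. Genes named outside this rule were chosen after their values were seen, and this applies to the haemoglobin, immunoglobulin and Y-linked genes, Xist, Jchain, Ngp, Ltf, Nfe2, Zfpm1, Gm20532, Il17re, Myl10 and the models without a proper symbol among the genes past the threshold. Some genes that the rule names are not reported here.

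Coordinates and gene types come from GENCODE release M21 on GRCm38, which is mm10, and 46005 of the 46517 gene identifiers matched it. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at TPM 5, scaling by trimmed means of M values (30% trim of M and 5% of A, unweighted), by median-of-ratios factors or by quantiles, moderation without the trend or with robust estimation, a replicate block, and each library left out in turn. A further 3, given in the closing part on processing, were chosen after seeing the data. Alternatives planned in case of counts were not run.

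TPM keeps no read total. Among genes of 400 to 1500 nt with 1 annotated transcript, TPM multiplied by length nevertheless clustered at a lowest step in each library, which was taken as the worth of 1 read. In Setd2f/f replicate 1, 249 genes lay within 0.15 of 1 step and 48 within 0.15 of 1.5 steps. Relative to Setd2f/f replicate 2, the inverse of this step gave a depth of 0.840 for Setd2f/f replicate 1, 0.616 for Setd2D/D replicate 1 and 0.906 for Setd2D/D replicate 2. Read numbers derived from this step are estimates, so no interval for counting error is given.

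The procedure was tested on simulated data with the means of the 14755 genes and variances drawn around the fitted trend. Over 10 simulations of 200 changed genes, limma recovered 0.900% of those changed by log2 1 and 27.2% of those changed by log2 2, with a mean of 1.50 unchanged genes called. A list shifted by log2 1 was called by camera in 10 of 10 simulations. The simulated genes were independent of each other. In the real lists the estimated correlation was 0.096 for erythroid, 0.59 for MYC ribosome biogenesis and 0.64 for mitochondrially encoded genes. The simulation therefore does not give the error rate of camera for correlated lists, or its power for smaller shifts. Python 3.11.15 with scipy 1.17.1 was used for the remaining checks.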

Results

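Gene expression was measured by mRNA sequencing in LSK cells of mice with functional Setd2 (Setd2f/f, 2 libraries) and of mice in which Setd2 was knocked out (Setd2D/D, 2 libraries). Setd2 is the methyltransferase that places the trimethyl mark on lysine 36 of histone H3 in transcribed gene bodies. The design compares the 2 genotypes, and the study's title asks how Setd2 acts on the quiescence and differentiation of adult haematopoietic stem cells. Levels are given as the mean TPM ± SD (n = 2 libraries). Between 14360 and 14610 genes reached a TPM of 1 in a library. The shallowest library, by the worth of 1 read, was Setd2D/D replicate 1, at 0.616 of the depth of Setd2f/f replicate 2. The Setd2f/f libraries correlated at r = 0.96 across genes and the Setd2D/D libraries at r = 0.91, where genes are not independent replicates. Setd2D/D replicate 1 stood apart, at r = 0.91 with each Setd2f/f library too, while Setd2D/D replicate 2 correlated with these at r = 0.93 and 0.94, above its value with its own replicate. All 4 libraries carried Y-linked transcripts, with Ddx3y between 35.0 and 48.6 TPM, and Xist did not exceed 0.200 TPM in any of them.

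Setd2 (ENSMUSG00000044791, GRCm38 chromosome 9, 110532597 to 110618633) was lower in both knockout libraries. Its level was 78.9 and 68.0 TPM in the Setd2f/f libraries and 43.4 and 49.5 TPM in the Setd2D/D libraries, a ratio of mean TPM of 0.633. In the limma fit the log2 change was -0.65 with an SE of 0.15, and the adjusted p was 0.329 over all genes and 0.0351 adjusted over the list alone for the 24 measured regulators fixed in advance, but 0.106 adjusted over the 16 measured H3K36 methylation enzymes alone, also a planned list. The authors' deposited table gives Setd2 a log2 change of -0.73 with an FDR of 5.84e-06. The value covers the whole gene, and transcripts that lack only the deleted part would still be counted. Among other enzymes that act on H3K36, the demethylase gene Kdm4b was at 21.7 ± 2.09 TPM in Setd2f/f and 12.6 ± 0.424 in Setd2D/D, a ratio of 0.581 (limma adjusted p = 0.358), and Kdm2b at 74.3 ± 4.60 and 56.2 ± 21.4. Of the methyltransferases, Nsd1 was at 33.1 ± 0.658 TPM in Setd2f/f and 32.4 ± 0.240 in Setd2D/D, Whsc1 (Nsd2) at 98.4 ± 13.4 and 89.2 ± 16.2, Whsc1l1 (Nsd3) at 54.1 ± 6.31 and 52.1 ± 0.820, and Ash1l at 26.7 ± 3.03 and 22.7 ± 0.721. Of the 16 enzymes, 0 passed limma over all genes or adjusted over the list alone, and in the authors' deposited table Setd2 was the 1 member past an FDR of 0.05. Dot1l, which methylates lysine 79 of H3, was at 43.2 ± 0.0566 and 39.7 ± 1.72 TPM.

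Genes of the erythroid lineage were higher in Setd2D/D LSK cells. Car1, an erythroid carbonic anhydrase, was at 32.1 ± 13.4 TPM in Setd2f/f and 144 ± 16.3 in Setd2D/D, a ratio of 4.48. Klf1, a transcription factor of red cell development, was at 4.58 ± 0.0354 and 19.4 ± 0.438 TPM, Gata1 at 10.2 ± 1.03 and 22.5 ± 5.28, and the water channel gene Aqp1 at 12.4 ± 0.552 and 31.6 ± 4.21. The erythroid list of 27 measured genes had a mean log2 change of 1.24 (SD 1.20 across members) with 23 members above 0, and rose by camera with an adjusted p of 2.88e-12. This call was lost with the estimated correlation (adjusted p = 0.822) and with fry (adjusted p = 0.0727). Adjusted over the list alone, 14 members rose and 2 fell by limma, the latter being Nfe2 and Zfpm1. In the authors' deposited table, 15 members were higher, 0 were lower and 12 did not pass. Only Mt2 passed limma over all genes. Mt2 (chromosome 8, 94172664 to 94173568) encodes a metal-binding metallothionein and was at 3.68 ± 0.410 TPM in Setd2f/f and 72.6 ± 0.424 in Setd2D/D, a ratio of 19.7 (limma log2 change 3.98, SE 0.19, adjusted p = 0.0224). The neighbouring Mt1 was at 20.3 ± 2.61 and 87.4 ± 12.7 TPM and did not pass limma (adjusted p = 0.0859). Summed over Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, whose near-identical copies make the split between genes uncertain, haemoglobin transcripts were at 59.4 and 113.5 TPM in the Setd2f/f libraries and at 354 and 271 TPM in the Setd2D/D libraries. The list of heme synthesis genes did not pass camera (14 measured, mean log2 change 0.14, adjusted p = 0.145). Adjusted over the list alone 1 rose and 0 fell by limma, and in the authors' deposited table, 2 were higher, 0 lower and 12 did not pass. Ly6a, which encodes the Sca-1 antigen used in the sort, was at 126 ± 2.63 TPM in Setd2f/f and 63.6 ± 24.1 in Setd2D/D, and Kit, which encodes c-Kit, at 237 ± 17.2 and 293 ± 11.1. The authors' deposited table gives Ly6a a log2 change of -0.91 with an FDR of 3.08e-06 and Kit one of 0.35 with an FDR of 0.113. By limma over all genes, Ly6a (adjusted p = 0.370) and Kit (adjusted p = 0.420) did not pass.

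**Figure D1:**
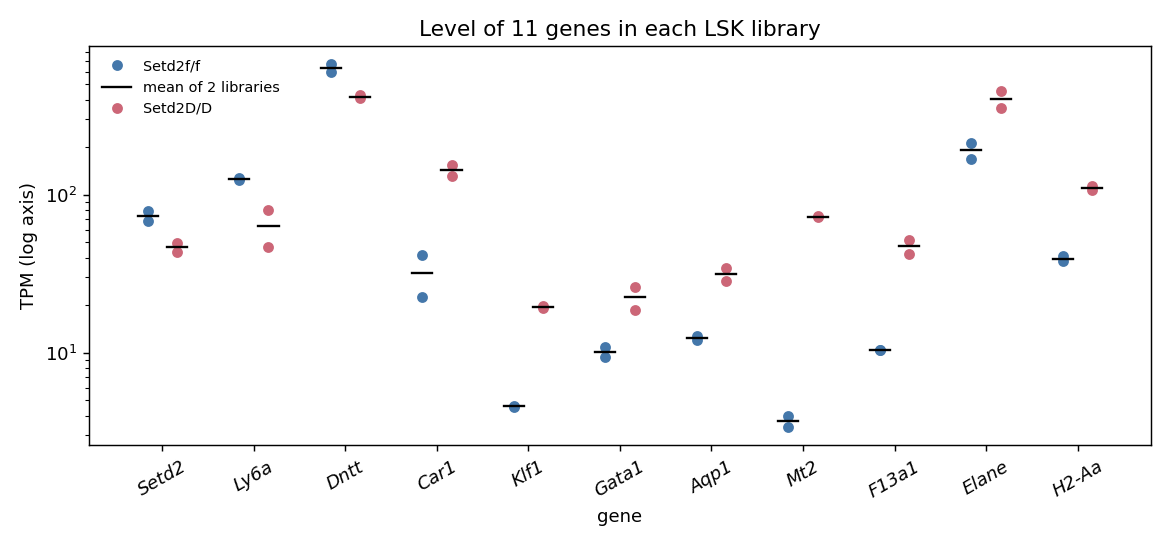
TPM on a log axis of 11 genes in each LSK library, with blue points for the 2 Setd2f/f libraries, red points for the 2 Setd2D/D libraries and black bars for the mean of 2 libraries. Setd2, Ly6a and Dntt have means of 73.5, 126 and 631 TPM in Setd2f/f and lower ones of 46.5, 63.6 and 417 in Setd2D/D, and the other 8 genes have higher means in Setd2D/D.

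Myeloid gene lists also had mean changes above 0, less evenly between the Setd2D/D libraries. Mpo, the myeloperoxidase of neutrophil precursors, was at 879 ± 89.9 TPM in Setd2f/f and 1652 ± 319 in Setd2D/D. Elane, the neutrophil elastase gene, was at 191 ± 31.8 and 403 ± 70.0 TPM, and F13a1, a coagulation factor gene of monocytes and megakaryocytes, at 10.4 ± 0.0566 and 47.1 ± 6.89. Csf3r, the receptor for granulocyte colony-stimulating factor, was at 147 ± 10.8 and 91.0 ± 13.6 TPM. The 31 measured granulocyte-monocyte genes had a mean log2 change of 0.19 (SD 0.75 across members), with 19 members above 0 and 12 below. The list rose by camera (adjusted p = 0.0126), but not with the estimated correlation (adjusted p = 0.871). Adjusted over the list alone 7 rose and 1 fell by limma, with 0 past the threshold over all genes, and in the authors' deposited table, 8 were higher, 3 lower and 20 did not pass. The 17 mast cell, basophil and eosinophil genes had a mean log2 change of 0.73 (camera adjusted p = 0.00360, and adjusted p = 0.822 with the estimated correlation). Of these, 4 rose and 1 fell adjusted over the list alone, and in the authors' deposited table, 5 were higher and 0 lower. Gzmb, a granzyme gene, was at 0.855 ± 0.148 and 10.2 ± 2.58 TPM. Without Setd2D/D replicate 2 both calls ended, with an adjusted p by camera of 0.844 for the granulocyte-monocyte list, whose mean was then -0.04, and 0.514 for the mast cell list, whose mean was then 0.38, against 1.08 without Setd2D/D replicate 1. Without Setd2f/f replicate 1 the granulocyte-monocyte call also ended (adjusted p = 0.152). The 13 measured macrophage genes lay at the threshold (mean log2 change 0.27, camera adjusted p = 0.0475, and adjusted p = 0.822 with the estimated correlation). They did not pass after any rescaling of the libraries, where the mean was between 0.28 and 0.32. The mean was 0.33 without Setd2f/f replicate 1 and 0.21 without Setd2f/f replicate 2. It was 0.20 without Setd2D/D replicate 1 and 0.35 without Setd2D/D replicate 2. Cd68, a lysosomal macrophage gene, was at 29.9 ± 5.35 and 67.2 ± 14.0 TPM.

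Genes of lymphoid priming, B cells and platelets included several with lower levels in Setd2D/D. Dntt, the terminal transferase of early lymphoid progenitors, was at 631 ± 51.6 TPM in Setd2f/f and 417 ± 13.5 in Setd2D/D, and Ctla2a at 195 ± 15.4 and 111 ± 10.2. The 28 lymphoid priming genes had a mean log2 change of -0.32 with 23 members below 0 and fell by camera (adjusted p = 0.0126), but not with the estimated correlation (adjusted p = 0.871). The mean was -0.49 without Setd2f/f replicate 2 and -0.16 without Setd2f/f replicate 1. It was -0.32 without Setd2D/D replicate 1 and -0.33 without Setd2D/D replicate 2. Adjusted over the list alone 2 fell and 0 rose by limma, and in the authors' deposited table, 5 were lower and 1 was higher. The 14 B lineage genes did not pass camera (mean log2 change -0.42, adjusted p = 0.147), but the value depended on single libraries, with a mean of -0.80 (adjusted p = 0.000863) without Setd2f/f replicate 2 and -0.05 (adjusted p = 0.818) without Setd2f/f replicate 1, and in the authors' deposited table, 9 of them were lower and 0 higher. Among them Cd79a, part of the B cell receptor, was at 83.2 ± 38.1 and 37.4 ± 4.72 TPM, and Vpreb1, part of the precursor B cell receptor, at 83.1 ± 34.5 and 27.5 ± 14.0. The 10 T and NK cell genes (camera adjusted p = 0.392) and the 9 stromal and endothelial genes (camera adjusted p = 0.142, fry adjusted p = 0.0305) had mean log2 changes of -0.50 and -0.71, which were -0.29 for each list with no filter. The endothelial gene Emcn was at 33.6 ± 13.1 and 8.69 ± 4.26 TPM. Megakaryocyte and platelet genes moved both ways, with 5 rising and 5 falling of 23 adjusted over the list alone and a camera adjusted p of 0.920, and in the authors' deposited table, 1 was higher, 6 were lower and 16 did not pass. Nrgn was at 86.9 ± 13.2 and 50.3 ± 0.0495 TPM, and Pf4, platelet factor 4, at 12.3 ± 1.48 and 39.9 ± 4.55.

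The 36 stem cell and quiescence genes did not shift as a list by camera (mean log2 change 0.03, median -0.033, adjusted p = 0.920). Adjusted over the list alone 0 passed, and in the authors' deposited table, 3 were higher, 2 were lower and 31 did not pass. Hlf was at 173 ± 34.2 TPM in Setd2f/f and 146 ± 5.89 in Setd2D/D, Procr at 48.5 ± 13.8 and 46.7 ± 15.6, Mecom at 26.8 ± 2.15 and 32.2 ± 6.39, and Gata2 at 84.0 ± 2.93 and 82.6 ± 15.5. Tek, the angiopoietin receptor gene, was at 4.76 ± 0.170 and 14.0 ± 1.67 TPM and Gata3 at 6.12 ± 0.156 and 13.3 ± 4.67. The authors' deposited table gives them log2 changes of 1.42 and 1.13 with an FDR of 7.46e-07 and 0.00532. Neither passed limma over all genes (adjusted p = 0.255 and 0.415). Among cell cycle genes, Mki67 was at 150.3 ± 0.672 and 150.0 ± 2.26 TPM and the cyclin-dependent kinase inhibitor gene Cdkn1c at 5.45 ± 0.707 and 4.42 ± 1.02. The 29 mitosis genes rose slightly by camera (mean log2 change 0.13, adjusted p = 0.00464), but not with the estimated correlation (adjusted p = 0.822). The mean was 0.15 without Setd2f/f replicate 1 and 0.098 without Setd2f/f replicate 2. It was 0.11 without Setd2D/D replicate 1 and 0.14 without Setd2D/D replicate 2. Of the 29 genes 0 passed limma, over all genes or adjusted over the list alone. In the authors' deposited table, 1 was higher and 28 did not pass. Cdk1 was at 197 ± 6.07 and 251 ± 10.1 TPM. The 30 S phase genes did not pass (mean log2 change -0.06, camera adjusted p = 0.613), but fell without Setd2f/f replicate 1 (mean -0.15, adjusted p = 0.0215), while the mean was 0.02 without Setd2f/f replicate 2 (adjusted p = 0.445). The 30 ribosome biogenesis targets of MYC rose by camera (mean log2 change 0.10, adjusted p = 0.0126), but not with the estimated correlation (adjusted p = 0.871), without Setd2f/f replicate 1 (mean -0.06, adjusted p = 0.918) or without Setd2D/D replicate 2 (adjusted p = 0.274). Npm1 was at 1919 ± 137 and 2438 ± 104 TPM, while Myc itself was at 334 ± 38.9 and 283 ± 11.2. The 41 Pol II elongation factors did not pass camera (mean log2 change -0.03, adjusted p = 0.927), and 0 of them passed in limma over all genes, adjusted over the list alone or in the authors' deposited table.

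The 14 mitochondrially encoded genes rose by camera (mean log2 change 0.15, adjusted p = 0.00205), but not with the estimated correlation (adjusted p = 0.871), and without Setd2f/f replicate 2, Setd2D/D replicate 1 or Setd2D/D replicate 2 the adjusted p was 0.123, 0.0717 and 0.0532. The mean was 0.36 without Setd2f/f replicate 1, but -0.06 without Setd2f/f replicate 2 and -0.09 with no filter. The members did not move as one, since mt-Atp8 was at 6184 ± 374 and 10856 ± 508 TPM and mt-Co2 at 682 ± 173 and 238 ± 112, and the authors' deposited table has 6 members higher and 1 lower. Class II antigen presentation genes split in the same way. H2-Aa (chromosome 17, 34282744 to 34287823), a class II chain, was at 39.3 ± 2.06 and 110 ± 4.72 TPM, H2-Eb1 at 25.4 ± 5.45 and 72.0 ± 2.33 and H2-Ob at 83.4 ± 16.0 and 38.3 ± 5.07, with 10 members above 0 and 9 below, and the list of 19 did not pass camera (mean log2 change 0.22, adjusted p = 0.0626, and between 0.0222 and 0.187 under the alternatives at the preset correlation), although 3 members rose and 1 fell adjusted over the list alone. The other lists, covering H3K36 methylation enzymes and readers, p53 targets, DNA repair, interferon response, adhesion and niche retention, HOX genes and cofactors, glycolysis, oxidative phosphorylation, ribosomal proteins, immediate early and dissociation stress, unfolded protein and amino acid stress, replication-dependent histones, apoptosis regulators, polycomb and DNA methylation, splicing factors, and the fixed regulators, had camera adjusted p-values between 0.197 and 0.927. Fry called the stromal and endothelial list and the apoptosis list (adjusted p = 0.0305 for each).

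**Figure D2:**
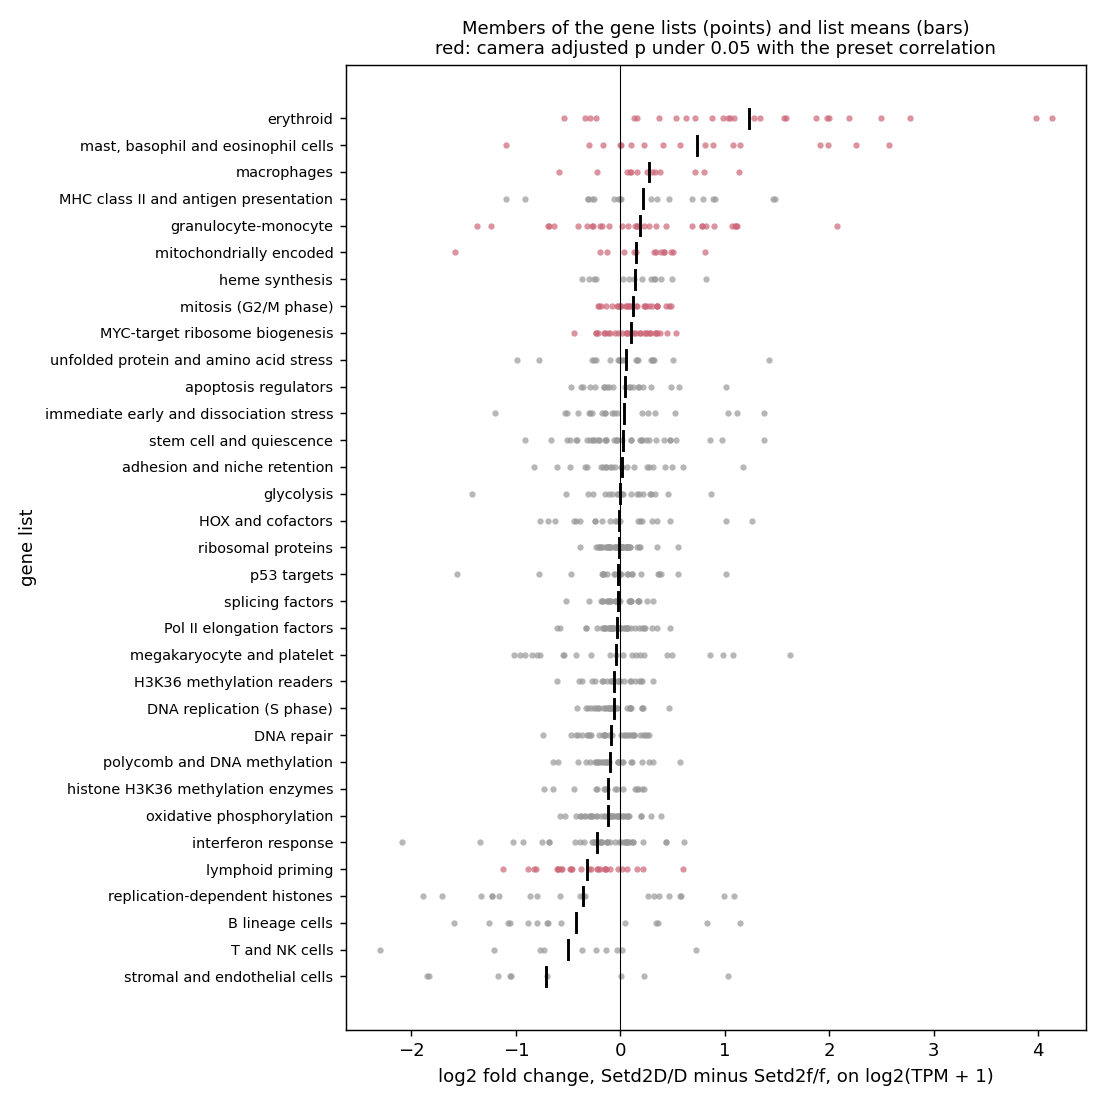
Log2 fold change of each measured member (points) of 33 gene lists, Setd2D/D minus Setd2f/f on log2(TPM + 1), with the list mean as a black bar and red points for lists with a camera adjusted p under 0.05 at the preset correlation. The erythroid list has the highest mean, 1.24, and the stromal and endothelial list the lowest, -0.71.

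Over all 14755 genes tested, limma placed 10 past an adjusted p of 0.05, 3 higher and 7 lower in Setd2D/D, and 1647 genes had an unadjusted p under 0.05. Mt2 was the 1 protein-coding gene among them outside the immunoglobulin loci. The immunoglobulin segment Igkv10-94 (chromosome 6, 68704508 to 68704978) was listed at 0 in both Setd2f/f libraries and at 99.8 and 60.0 TPM in the Setd2D/D libraries, and Igkv17-127 (chromosome 6) at 40.9 and 72.4 TPM in Setd2f/f and at 0 in both Setd2D/D libraries. Ighg1, the constant region of IgG1, was at 21.5 and 21.9 TPM in Setd2f/f and at 0 and 0.03 TPM in Setd2D/D. The other 6 were the small RNAs Scarna17, Snord66 and Mir6357, the models AC122428.1 and Gm27320, and the processed pseudogene Gm10156. Of the 10, 8 had merged exons under 500 nt, against 6.06% of the tested genes, 8 were listed at 0 in both libraries of 1 genotype, and 4 (Scarna17, Snord66, Mir6357 and Gm27320) did not pass the FDR of the authors' deposited table. At such short lengths a few reads give a high TPM. When any 1 library was left out, limma placed 0 genes past the threshold, with the lone library of its group assumed to vary like the other pair, and the unadjusted p was under 0.05 for between 554 and 2928 genes.

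Genes next in rank did not pass limma over all genes. Higher in Setd2D/D were Bex4 (chromosome X, 11.1 ± 0.792 against 74.9 ± 11.9 TPM, adjusted p = 0.0534), H2-Aa, Mt1, F13a1, the imprinted non-coding RNA Rian (5.65 ± 0.955 against 30.2 ± 2.84 TPM), Trbv13-2, Isyna1, which makes inositol phosphate (64.6 ± 9.77 against 158 ± 8.34 TPM), and Ighv10-3, with limma adjusted p-values up to 0.122. Lower were Igkv16-104, Igkv8-27, Igkv5-43, Snora34 and Eif4ebp3, the last listed at 12.2 and 15.6 TPM in Setd2f/f and at 0 in both Setd2D/D libraries, with adjusted p-values up to 0.0859.

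The authors' deposited table places 754 genes past an FDR of 0.05, 362 higher and 392 lower in Setd2D/D, of which 596 are protein-coding. With an absolute log2 change of at least 1 as well, the authors' deposited table has 357 genes, 205 higher and 152 lower. Of those 754 genes in the authors' deposited table, 706 were tested by limma, 703 had the same sign there, 516 had an unadjusted p under 0.05 and 6 an adjusted one. Both libraries of 1 genotype lay on the same side of both of the other for 641 of these 706 genes. Those genes were picked for differing between these same libraries, so this is no separate support. Of all tested genes 44.3% lay so, where chance gives 33.3% if the libraries are exchangeable. The shares for splits that mix the genotypes were not computed, so this excess is not assigned to genotype.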

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

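The protein-coding restriction, the correction for GC content and length, and the rescaling without mitochondrial genes were chosen after seeing the data. The lower level of Setd2 kept its direction under every alternative, with log2 changes from -0.75 to -0.54, and passed the adjusted threshold of limma under none (adjusted p from 0.197 to 0.949). The erythroid call held under every alternative that kept camera's preset correlation (highest adjusted p 1.12e-05). Read totals are unknown, and Setd2D/D replicate 1 was the shallowest library at 0.616 of the depth of the deepest.

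The 10 genes past the threshold became 3 with a pseudocount of 0.1, 0 with no filter, 19 without the variance trend (9 of the 10 among them), 4 after the correction for GC content and length, and 0 whichever of the 4 libraries was left out. They stayed within 1.5 times elsewhere, apart from the replicate block. The 9 genes past it among protein-coding genes of at least 500 nt shared 1 gene, Mt2, with the 10, and were otherwise Bex4, Eif4ebp3, F13a1, Gm20532, H2-Aa, Il17re, Mt1 and Myl10. The restriction and the loss of a library change the number of genes or samples by construction. For the others the cause was not tested. Without a filter 2035 genes had an unadjusted p under 0.05.

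With the replicate number as a block, which leaves 1 residual degree of freedom, limma placed 0 genes past the threshold, 1508 having an unadjusted p under 0.05, and camera placed 8 lists. Replicate differences of both groups correlated at r = 0.04 across genes, which does not exclude that numbers pair libraries.

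Of the 8 lists, 0 were kept with an estimated correlation and 0 with fry, which called 2 others, the stromal and endothelial and the apoptosis lists. With a library left out, 5 were kept without Setd2f/f replicate 1, 6 without Setd2f/f replicate 2, 6 without Setd2D/D replicate 1 and 1, the erythroid list, without Setd2D/D replicate 2. Some alternatives called lists outside the 8. Without Setd2f/f replicate 1 these were S phase (adjusted p = 0.0215), oxidative phosphorylation (0.00612, mean log2 change -0.18) and class II antigen presentation (0.0293), and without Setd2f/f replicate 2 they were B lineage (0.000863) and glycolysis (0.0186, mean log2 change 0.06). B lineage was also called with the filter at TPM 5 (0.0371, mean log2 change -0.68), and class II with median-of-ratios scaling (0.0491) and after the GC and length correction (0.0222). With the estimated correlation the adjusted p was 0.822 for the erythroid, mast cell, mitosis and macrophage lists and 0.871 for the granulocyte-monocyte, lymphoid priming, MYC ribosome biogenesis and mitochondrially encoded lists. With fry it was 0.0727 for erythroid, 0.366 for mast cell, 0.307 for mitosis, 0.467 for macrophage, 0.467 for granulocyte-monocyte, 0.366 for lymphoid priming, 0.781 for MYC ribosome biogenesis and 0.548 for mitochondrially encoded genes. Leaving out a library moved it from 0.00612 to 0.0781 for mitosis, 1.05e-07 to 0.918 for MYC ribosome biogenesis, 1.93e-05 to 0.844 for granulocyte-monocyte, 0.000632 to 0.355 for lymphoid priming, 1.08e-05 to 0.514 for mast cell, 0.0398 to 0.187 for macrophage and 1.66e-07 to 0.123 for mitochondrially encoded genes. The macrophage list had 0.0540 with no filter, 0.0502 with the filter at TPM 5, 0.0709 with scaling by trimmed means, 0.0682 by median of ratios and 0.114 by quantiles, 0.0543 without the trend, 0.0595 after the GC and length correction and 0.0582 without mitochondrial genes. MYC ribosome biogenesis had 0.0543 without the trend, lymphoid priming 0.0584 with the filter at TPM 5, and mitochondrially encoded genes 0.122 with quantile scaling. The cause was not tested. The stromal and endothelial mean log2 change was -0.29 with no filter, where B lineage was lowest at -0.38, and -1.32 with a pseudocount of 0.1. Rescaling without mitochondrial genes leaves no value for their own list. The authors' deposited table went from 754 to 357 genes with the added minimum on the log2 change, which its construction explains. Alternatives that need counts were not run.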

Other observations

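All tests given in these paragraphs were chosen after the values had been seen, although the test on gene length was set before its own outcome was. The immunoglobulin constant regions Igkc, Ighm and Igha followed the replicate number more closely than the genotype, so pairing by number stays open. Igha was lower in replicate 1, at 287 and 324 TPM in Setd2f/f and 281 and 327 in Setd2D/D, and the other 2 were higher. Igkc was at 2746 and 1861 TPM in Setd2f/f replicates 1 and 2 and at 2644 and 1777 in the Setd2D/D replicates, and Ighm at 1923 and 1326 against 1776 and 1185. Jchain, the joining chain of secreted antibodies, was at 256 and 175 against 194.5 and 157 TPM. The IgG constant regions did not follow this, with Ighg2b at 81.4 and 109.8 TPM in Setd2f/f against 8.16 and 34.6 in Setd2D/D, and Ighg2c at 33.1 and 52.9 against 7.44 and 3.68. Ngp and Ltf, granule protein genes of maturing neutrophils, went against Mpo and Elane in the authors' deposited table, with log2 changes of -0.90 and -0.96.

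Fewer immunoglobulin V segments were seen in Setd2D/D, with 79 and 88 of 182 above 0 TPM against 127 and 150 in Setd2f/f. Lower depth of Setd2D/D replicate 1 is argued against as the whole cause. Setd2D/D replicate 2 had 88 segments at a relative depth of 0.906, and Setd2f/f replicate 1 had 127 at 0.840. The Setd2f/f level would give an estimated 20 reads or more in Setd2D/D replicate 1 for 110 segments. Of these, 27 were at 0 in both Setd2D/D libraries, against 7 of 93 in the opposite direction and 99 of 12662 protein-coding genes. The worth of 1 read was set on genes longer than segments such as Igkv10-94 (347 nt). The cut at 20 reads is therefore uncertain for V segments and alone does not decide. Less immunoglobulin RNA is argued against too, since the total over V segments was 1.01 times that of Setd2f/f while the number seen was 0.603 times. Reads shared between V segments of near-identical sequence stay open, because pairs of libraries that mix the genotypes also had up to 14 such segments at 0 in both. A different set of B cell clones in the mice sampled, or an effect of the knockout on them, may also account for it and was not tested. The lineage gate of the sort should exclude B cells, yet V segments totalled between 2745 and 3561 TPM in each library. The gate is therefore no argument against either explanation. With 2 libraries per genotype these explanations cannot be told apart.

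The rise of the erythroid list was weighed against 3 technical explanations. After correction for GC content and length its mean log2 change was 1.33 (SD 1.21 across members) against 1.24 (SD 1.20) before, so that trend is argued against as the whole cause. For a lower share of LSK cells in the Setd2D/D sort, the erythroid list was compared with the B lineage list. The erythroid mean was higher by 1.66 on the log2 scale (permutation p = 4e-05 over 27 and 14 member genes, which are not independent replicates). It was higher by at least 1.38 whichever library was left out. Both list means had been seen before this test was chosen, and the B lineage members had an estimated correlation of 0.66. The permutation p is therefore no separate support. The difference in means argues only against an admixture that adds erythroid and B lineage cells evenly. An uneven admixture stays open, as the mast cell, macrophage and granulocyte-monocyte lists also had means above 0 (0.73, 0.27 and 0.19). A small share of erythroid progenitors among the sorted Setd2D/D cells stays open, although the Sca-1 gate should exclude them, since the stem cell list had a median log2 change of -0.033 (SD 0.46), which a small share would leave in place. Ly6a, which encodes Sca-1, was at 126 ± 2.63 TPM in Setd2f/f and 63.6 ± 24.1 in Setd2D/D (limma adjusted p = 0.370). A small share would not by itself give such a fall, but 1 gene does not decide. Such a share cannot be told apart here from erythroid gene expression within LSK cells after loss of Setd2.

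The study's title names RNA polymerase II elongation, and a hypothesis drawn from it is that loss of Setd2 changes long genes more than short ones. Across 12077 protein-coding genes, which are not independent replicates, gene length and the absolute log2 difference between the genotype means had a Spearman rho of -0.0256. The other 2 ways to part the 4 libraries into pairs, which mix the genotypes, gave -0.0391 and -0.0280. The first lay above the second of these by less than the 2 differ from each other, so the test does not decide, and with 3 such splits the hypothesis stays open at the level of total gene TPM.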
